A study of Homo sapiens with 5 samples.

How the data were processed

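Total RNA from enzalutamide-resistant LNCaP cells was labelled with biotin and hybridised to 5 Illumina bead arrays, per the labels' protocols: 2 from cells given water and 3 from cells given 50 µM dilazep for 48 h. Group and replicate number were taken from the sample labels, and array columns were matched to samples through the sample numbers in the descriptions. No column belonged to a sample outside these groups. The deposited scanner table held, per probe and array, a linear intensity without normalization and a detection p-value, per the file headers. It had 47422 rows, of which 99 repeated another row with identical values and were used once, leaving 47323 probes. The smallest intensity was 77. The authors' deposited value table held log2-like expression values for 21534 of these probes, and per the submitters' processing notes the R package lumi was used (version not given in the sources used here). Set against the raw intensity of the same array, each column of that table had a Spearman correlation that rounded to 1. Its slope on log2 intensity was 0.635 among the dimmest probes and 1.02 among the brightest, so dim probes were compressed as by a variance-stabilising transform. Its column medians lay at 7.78, and the values were not centred per gene. The exact transform and its options stayed unknown, and the table was used as an alternative.

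Intensities were background-corrected with normexp (parameters from the detection p-values, offset 16), quantile normalized and log2 transformed with neqc in limma 3.58.1 under R 4.3.3. The offset pulls log2 fold changes of dim probes towards 0. A probe was kept where its detection p was under 0.05 on at least 2 of the 5 arrays, whatever their group, which left 20200 probes. Gene symbols came from the platform annotation, which can be old. It gave 1 symbol for 15827 probes of the authors' table, several for 4 and none for 5703. Gene IDs of 15816 of the first matched a table of current human genes (GRCh38.p14), and 0 symbols changed; no coordinates were used. Of the kept probes 14564 had 1 symbol and 5636 had not. The latter included 1080 probes outside the authors' table, which the annotation did not cover. Probes without a single symbol stayed in the variance model and out of the gene counts. Each gene was represented by its brightest kept probe over the 5 arrays, which gave 11010 genes, 2878 of them with more than 1 kept probe.

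Dilazep was compared with water by lmFit and eBayes in limma on all 5 arrays without a block (3 residual and 3.90 prior degrees of freedom), with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. Differences are dilazep minus water on the normalized log2 scale, with the SE of the fit; a level is the mean ± SD of its group. A probe at or below background on every array of a group had only a bound there. The fold is then given as "at least", from the bright group's mean against the dim group's mean of the higher of the lowest detected signal and the probe's own signal on each array.

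Gene lists were written before the data were examined. The 24 lists with at least 5 measured members were tested with camera (limma, inter-gene correlation preset at 0.01), adjusted over these lists; an estimated correlation and fry, which asks whether a list's genes move without comparing them with other genes, were alternatives. Named genes followed a rule also set beforehand. It took the 10 highest and 10 lowest genes past the threshold whose groups did not overlap, leaving out provisional gene names and sex-linked marker genes, and 12 single genes of interest. From each list it took up to 4 members past the threshold with the largest change, or up to 2 where none passed, given as values. SLC29A1 had its annotated probe below the detection filter, and GATA3, KLK3, NR3C1 and IGF2 were not analysed here; 1 of the 12 is not reported here. Python 3.11.15 with matplotlib 3.10.9 drew the plots.

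The gene and list tests were tested on simulated data built from these arrays, 20 times, with 200 of 11010 genes changed. For dilazep against water, 45.6% of genes changed by 1 on the log2 scale and 87.4% of those changed by 2 were called, and 4.51% of calls were false. A list of 30 genes shifted by 0.6 was called in 20 of 20 simulations and an unshifted list in 0, at an unadjusted camera p under 0.05. Genes were drawn independently from the levels and fitted spread of these arrays. The simulations thus cannot show how the list test behaves for genes that vary together. Nor can they show the share of false gene calls where the spread departs from the fitted model. The alternatives tried were no background correction, an offset of 50, median and 75th percentile scaling, the authors' values, no detection filter, a detection p under 0.01 on all 5 arrays, the mean of a gene's probes, a trended robust prior, array weights, the replicate number as a block, stricter thresholds and each array left out in turn. The lone water array was then assumed to vary like the dilazep arrays.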

Results

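Gene expression was measured on 5 one-colour Illumina bead arrays in a derivative of LNCaP, a human prostate cancer line that grows in response to androgen. The derivative had been selected in 25 µM enzalutamide (MDV-3100), an antiandrogen, and was kept at 10 µM during the experiments. Cells received either 50 µM dilazep, known as an inhibitor of equilibrative nucleoside transport, or water for 48 h. The design held 2 water arrays and 3 dilazep arrays, and their number limits the precision of every value. Detected probes (detection p under 0.05) numbered 20058 and 18886 on the water arrays and 18853, 19493 and 19004 on the dilazep arrays. Median raw signals were 122.1 and 123.5 with water and 118, 120 and 119.6 with dilazep. Across probes, normalized log2 signals correlated at 0.991 between the water arrays, at 0.9855 to 0.986 among the dilazep arrays and at 0.9779 to 0.9787 between groups. Genes are not independent replicates in these correlations. Neither labels nor files tied the replicates of a group to separate cultures, so p-values by gene measured only the spread between these arrays, which may be technical. List p-values from camera with the preset correlation, and from the permutation of genes, rest on the spread between genes and not on that between arrays. They therefore say little about replication.

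The title of the series gives GATA2, a zinc finger transcription factor of prostate luminal cells, as the target, and its own transcript was the first value examined. GATA2 was higher with dilazep, at a normalized log2 signal of 9.82 ± 0.04 (SD, n = 3) against 8.98 ± 0.08 (SD, n = 2). The difference of 0.84 (SE 0.13, log2) was a 1.79-fold rise with a limma adjusted p of 0.0250, and each dilazep array lay above both water arrays. TMPRSS2, an androgen-regulated serine protease, rose 1.95-fold (limma adjusted p = 0.0301). FOXM1, a transcription factor of mitotic genes, fell 2.08-fold (limma adjusted p = 0.0308), and its further kept probe differed by −0.67. FOXA1, a pioneer transcription factor, differed by 0.09 ± 0.13 (SE), and HOXB13, a homeobox factor of prostate epithelium, by 0.13 ± 0.18. MYC differed by −0.58 ± 0.15 and did not pass (limma adjusted p = 0.0738), though it did under 6 of 16 other settings. Its further kept probe differed by −0.29. The GATA2 log2 fold change rested on 1 probe, and its adjusted p was 0.188 and 0.201 without water replicate 1 and 2, and 0.0695, 0.0658 and 0.0614 without dilazep replicate 1, 2 and 3. TMPRSS2 and FOXM1 did not pass in these refits either, and GATA3, KLK3, SLC29A1, NR3C1 and IGF2 were not analysed here.

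**Figure D1:**
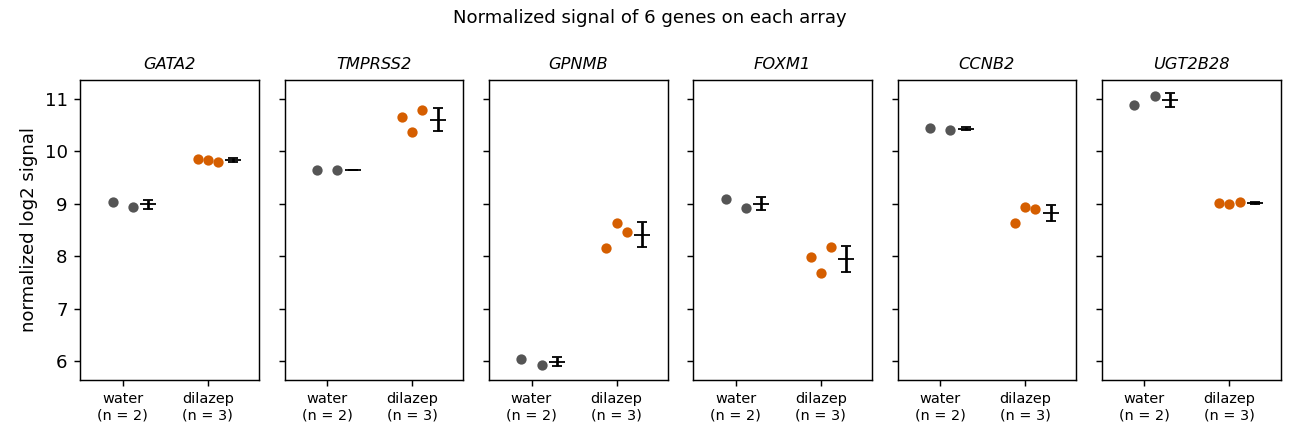
Normalized log2 signal (vertical axis) of 6 genes on each array, with water (n = 2) in grey and dilazep (n = 3) in orange; the short line and bar beside the points give the mean and SD of each group. GATA2, TMPRSS2 and GPNMB lay higher on every dilazep array than on either water array, and FOXM1, CCNB2 and UGT2B28 lay lower.

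Among all genes, GPNMB, a lysosomal and melanosomal membrane glycoprotein, had the largest rise in the main fit, 5.35-fold (log2 2.42, SE 0.18, limma adjusted p = 0.00760). SAT1, the acetyltransferase that begins polyamine breakdown, followed at 4.91-fold (log2 2.30, SE 0.15). UAP1L1 rose 3.39-fold, OPTN, an autophagy receptor, 3.24-fold, TMEM116 3.13-fold, TM7SF2, a sterol reductase, 3.11-fold and PGAP6 3.09-fold. HSD17B14, a hydroxysteroid dehydrogenase, rose 3.01-fold, SPON2, a secreted matrix protein, 2.91-fold and ZC3H12A, an RNase of immune transcripts, 2.76-fold. The largest fall in the main fit was in TM4SF1, a small membrane protein of epithelial tumours, 5.93-fold (log2 −2.57, SE 0.20, limma adjusted p = 0.00760). RNLS, a flavoprotein oxidase, fell 4.39-fold, SLC7A5, a transporter of large neutral amino acids, 4.11-fold, the neuropeptide GAL 3.94-fold and UGT2B28, a glucuronosyltransferase, 3.87-fold. EFHC2 fell 3.69-fold, VAV3 3.63-fold, the orphan nuclear receptor NR2F1 3.52-fold, the chloride channel BEST1 3.22-fold and the secreted glycoprotein STC1 3.12-fold. Some of these rested on dim or disagreeing probes. The further probe of UAP1L1 differed by 0.02, that of VAV3 by −1.09, and those of RNLS by −1.69 and −0.08. RNLS and VAV3 probes were detected on 1 of 3 dilazep arrays, EFHC2 on 2 of 3, and HSD17B14 on 1 of 2 water arrays. Without water replicate 1 or 2 another RNLS probe became the brightest, and the gene's difference was then −0.02 and −0.15. Sizes and ranks of dim genes depended on the background correction, though each sign was kept. On the authors' values the log2 difference was 1.11 for GPNMB, 0.76 for UAP1L1, 0.47 for OPTN, 0.96 for PGAP6, 0.38 for HSD17B14 and 0.61 for SPON2. For the lower genes it was −1.17 for TM4SF1, −0.61 for RNLS, −0.77 for SLC7A5, −0.59 for EFHC2, −0.52 for VAV3, −0.52 for NR2F1, −0.60 for BEST1 and −0.73 for STC1. SAT1 (2.19 or more under each setting) then exceeded GPNMB, and UGT2B28 (−1.75) lay below TM4SF1; both orders also turned without background correction, and the first with an offset of 50.

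In total 546 of 11010 genes passed the threshold, 243 higher and 303 lower with dilazep (4.96% of genes, limma, Benjamini-Hochberg adjusted p under 0.05). A difference of at least 1 on the log2 scale was reached by 75 of the higher and 135 of the lower genes. The groups did not overlap in 46.8% of all genes, against 20% expected by chance for 2 arrays against 3, and in each of the 546. The counts depended on single arrays, with 0 genes called without water replicate 1 or 2 (1543 and 1576 at an unadjusted p under 0.05) and 90, 91 and 107 without dilazep replicate 1, 2 and 3. A further kept probe existed for 159 called genes and had the other sign in 14.

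**Figure D2:**
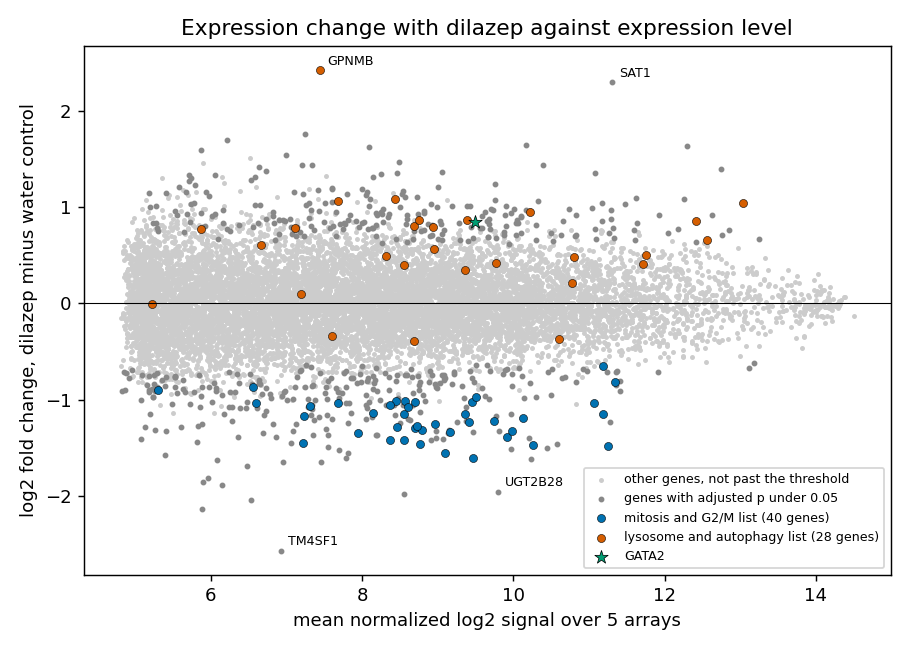
Log2 fold change with dilazep (vertical axis) against mean normalized log2 signal over the 5 arrays (horizontal axis), 1 point per gene. Genes past the threshold are dark grey, mitosis and G2/M genes blue, lysosome and autophagy genes orange and GATA2 a star; the 40 blue points all lay below 0, with a median of −1.18, and the orange points had a median of 0.59.

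Genes of cell division fell together. In the mitosis and G2/M list 35 of 40 measured genes fell and 0 rose, with all 40 lower when adjusted over the list alone and a median log2 change of −1.18. CCNB2, a mitotic cyclin, fell 3.04-fold (log2 −1.61, SE 0.15, limma adjusted p = 0.0102). DLGAP5, a spindle protein, fell 2.94-fold, PTTG1, the securin that holds back sister separation, 2.79-fold, and HMMR, a spindle and hyaluronan-binding protein, 2.78-fold. In the DNA replication and G1/S list 7 of 38 fell, or 25 when adjusted over the list alone, with a median of −0.51. RFC3, a clamp loader subunit, fell 1.93-fold, GINS4 and CDC45, of the replicative helicase, 1.90-fold and 1.84-fold, and POLA1, the catalytic subunit of DNA polymerase alpha, 1.81-fold. The medians of these lists differed by −0.67 (two-sided permutation of genes, p = 1e-05, the smallest that 100000 resamples can give; genes are not independent). Camera set both lists below the other genes (adjusted p = 2.60e-32 and 2.09e-10), while with an estimated correlation the adjusted p was 0.0580 for each. PTTG1 has a near-identical pseudogene that its probes may also read, GINS4 was detected on 2 of 3 dilazep arrays, and GINS4 and POLA1 did not pass with median scaling (adjusted p = 0.0519 and 0.0541), nor GINS4 on the authors' values (log2 −0.20, adjusted p = 0.0880).

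Genes of lysosomes and autophagy were higher. In this list 11 of 28 measured genes rose and 0 fell, with a median of 0.59, and 19 rose and 2 fell when adjusted over the list alone. Besides GPNMB, NEU1, a lysosomal sialidase, rose 2.12-fold (log2 1.08, SE 0.14, limma adjusted p = 0.0171), MCOLN1, a lysosomal calcium channel, 2.10-fold and SQSTM1, the p62 autophagy receptor, 2.06-fold. Camera set the list above the other genes (adjusted p = 1.98e-09), and with an estimated correlation the adjusted p was 0.0580.

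Lipid synthesis genes went both ways, and neither lipid list was called in the main fit. In the cholesterol list 3 of 19 rose, the same number when adjusted over the list alone. These were TM7SF2, the cyclase LSS (1.84-fold) and the desaturase SC5D (1.75-fold), and the list had a median of 0.09 (camera adjusted p = 0.288). In the fatty acid list of 15, SREBF1, the transcription factor of lipid synthesis, rose 1.70-fold and the desaturase SCD 1.59-fold, while the elongase ELOVL6 fell 1.72-fold. The median was 0.18 (camera adjusted p = 0.163), and 4 rose and 1 fell when adjusted over the list alone. On the authors' values the fatty acid synthesis shift was called (camera adjusted p = 0.0385), while with an estimated correlation on the main fit the adjusted p was 0.372. The further probes of SREBF1 differed by 0.08 and 1.03, and SCD did not pass with median or 75th percentile scaling (adjusted p = 0.0506 and 0.0585).

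Because GATA2 is known to act in the androgen response of prostate cells, androgen-induced and androgen-repressed genes were tested as lists. Of 23 measured androgen-induced genes, 2 rose and 1 fell, both over all genes and when adjusted over the list alone. ALDH1A3, an aldehyde dehydrogenase, rose 2.58-fold and TMPRSS2 1.95-fold, while CENPN, a centromere protein, fell 1.64-fold. On the authors' values ALDH1A3 differed by 0.49 (log2). The list was not called (camera adjusted p = 0.907), and its median of −0.11 was opposite in sign to its mean of 0.07 and to the direction of the test. Of 12 measured androgen-repressed genes 5 fell, or 6 when adjusted over the list alone, with a median of −0.48. UGT2B28, UGT2B11 and UGT2B15, of the UDP-glucuronosyltransferase family, fell 3.87-fold, 2.35-fold and 2.21-fold, and CAMK2N1, an inhibitor of CaM kinase, fell 2.76-fold. The fifth, UGT2B17, fell 1.75-fold and is named after its value was seen. Camera called this list (adjusted p = 0.00297), and with an estimated correlation the adjusted p was 0.149. The UGT2B genes are close paralogs whose probes may read each other's transcripts, so they are not separate evidence. The list was not tested without them. Among its members other than these and CAMK2N1, DDC (−0.70), LRRN1 (−0.26), BCHE (−0.05) and FOLH1 (−0.01) lay below 0. OPRK1 (0.10), MET (0.32) and ADD3 (0.41) lay above. Of 12 glucocorticoid-induced genes, TSC22D3, the leucine zipper factor GILZ, fell 2.34-fold and DUSP1, a MAP kinase phosphatase, rose 1.73-fold. Both counts were the same when adjusted over the list alone, and the list was not called (median 0.14, camera adjusted p = 0.685).

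Genes of the amino acid response driven by ATF4 were lower. In that list 6 of 30 fell and 0 rose, or 16 when adjusted over the list alone, with a median of −0.44. SLC7A5 fell 4.11-fold, SESN2, a leucine sensor, 2.39-fold and TRIB3, a pseudokinase, 1.78-fold (limma adjusted p = 0.0102, 0.0331 and 0.0265). CHAC1, which degrades glutathione, was not above background with dilazep and was at least 1.49-fold lower in the main fit (limma adjusted p = 0.0421). It did not pass without background correction, with an offset of 50, with median scaling, on the authors' values or with a trended robust prior (adjusted p = 0.101, 0.0589, 0.0545, 0.175 and 0.0579). Its log2 difference was −0.25 without background correction, −0.40 with the offset of 50 and −0.15 on the authors' values, all smaller than that bound. On the authors' values SESN2 differed by −0.33 (log2). Of 18 endoplasmic reticulum chaperones, PDIA6, a disulfide isomerase, fell 1.72-fold, and 4 fell when adjusted over the list alone (median −0.31). Of 20 ribosome biogenesis genes 0 passed, over all genes or over the list alone. Their median was −0.35, and MYC (−0.58, further probe −0.29) and the nucleolar methyltransferase FBL (−0.50) had the largest differences in the main fit. MYC passed under 6 and FBL under 4 of 16 other settings. Camera called the ATF4, chaperone and ribosome biogenesis lists (adjusted p = 2.88e-08, 0.00297 and 0.00297), and with an estimated correlation the adjusted p was 0.125, 0.276 and 0.149.

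**Figure D3:**
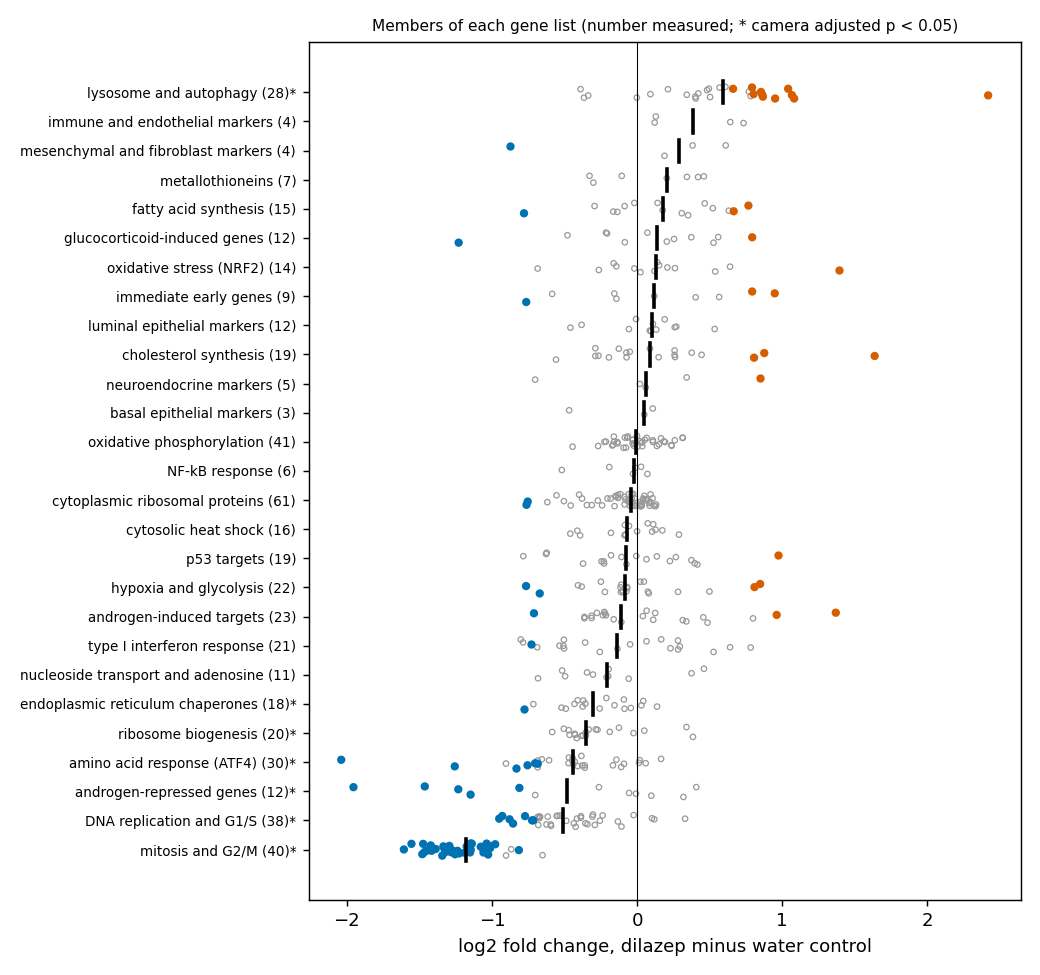
Log2 fold change with dilazep (horizontal axis) of each measured member of each gene list (vertical axis, number measured in brackets), with members past the threshold filled (orange higher, blue lower), the list median as a vertical bar and an asterisk where camera's adjusted p was under 0.05. The medians ran from −1.18 for mitosis and G2/M to 0.59 for lysosome and autophagy.

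The remaining stress and metabolic lists were not called in the main fit. Of 22 hypoxia and glycolysis genes, ENO2 and ALDOC rose 1.80-fold and 1.75-fold while HK2 and LDHA fell 1.70-fold and 1.59-fold, with 3 higher and 2 lower when adjusted over the list alone (median −0.09, camera adjusted p = 0.685). Of 14 oxidative stress genes FTL, the ferritin light chain, rose 2.63-fold, and 2 rose when adjusted over the list alone (median 0.13, camera adjusted p = 0.288). Of 19 p53 targets TP53INP1 rose 1.96-fold, with 1 higher and 1 lower when adjusted over the list alone (median −0.07, camera adjusted p = 0.907). Of 21 type I interferon genes IFIT1 fell 1.66-fold, and 3 fell when adjusted over the list alone (median −0.14, camera adjusted p = 0.216). Of 9 immediate early genes JUNB and DUSP1 rose 1.93-fold and 1.73-fold and KLF4 fell 1.70-fold, with 3 higher and 2 lower when adjusted over the list alone (median 0.12, camera adjusted p = 0.605). Of 61 cytoplasmic ribosomal protein genes RPL29 and RPS7 fell 1.70-fold and 1.69-fold, and 0 passed when adjusted over the list alone (median −0.04, camera adjusted p = 0.155). The cytoplasmic ribosomal proteins shift was called with median scaling (median −0.13, camera adjusted p = 5.49e-05), 75th percentile scaling (−0.19, 1.82e-05), the mean of probes (−0.08, 0.0151) and the authors' values (−0.05, 0.0385). With an estimated correlation on the main fit its camera adjusted p was 0.276. FTL, LDHA, RPL29 and RPS7 have many pseudogenes that their probes may also read. HK2, IFIT1 and RPL29 did not pass with median scaling (adjusted p = 0.0534, 0.0572 and 0.0562), and IFIT1 and KLF4 did not pass on the authors' values (0.0511 and 0.153), where JUNB differed by 0.35, IFIT1 by −0.23 and KLF4 by −0.15 (log2). KLF4, detected on 2 of 3 dilazep arrays, also did not pass without background correction (log2 −0.26, adjusted p = 0.0931) or with a trended robust prior (0.0531).

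In the next 5 lists 0 genes passed over all genes in the main fit. Among 11 nucleoside transport and adenosine genes, DCK, deoxycytidine kinase, differed by −0.68 (limma adjusted p = 0.0769) and the transporter SLC29A3 by −0.52 (limma adjusted p = 0.191). DCK passed under 5 of 16 other settings. When adjusted over the list alone, 1 gene was higher (SLC29A4, 0.46) and 2 were lower (DCK and ADORA2B, the latter at −0.50), while SLC29A3 did not pass. SLC29A4 and ADORA2B are named after their values were seen. That list had a median of −0.21 (camera adjusted p = 0.208). The 41 oxidative phosphorylation genes had a median of −0.01, opposite in sign to their mean of 0.0017 and to the direction of the test (camera adjusted p = 0.907), with NDUFS1 at −0.44 and SDHC at 0.32. The 16 cytosolic heat shock genes had a median of −0.07 (camera adjusted p = 0.685), with CACYBP at −0.46 and CHORDC1 at −0.41, whose further probe differed by 0.26. The 7 metallothionein genes had a median of 0.21 (camera adjusted p = 0.599), with MT1E at 0.46 and MT1H at 0.42, which passed under 3 of 16 other settings. The 6 NF-kB response genes had a median of −0.02 (camera adjusted p = 0.685), with TNFAIP2 at −0.52 and SOD2 at −0.19, whose further probe differed by −0.74. TNFAIP2 was detected on 1 of 3 dilazep arrays. When adjusted over the list alone, 0 genes passed in these last 4 lists.

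Markers of prostate luminal cells and of other cell types were examined last. Of 12 luminal markers 0 passed in the main fit, over all genes or over the list alone (median 0.10, camera adjusted p = 0.664), with the keratin KRT8 at 0.54 and the splicing factor ESRP1 at −0.46. KRT8 passed under 6 of 16 other settings. Of 5 neuroendocrine markers ENO2 rose, with 1 higher and 1 lower when adjusted over the list alone (median 0.06, camera adjusted p = 0.685). Fewer than 5 members of the other lists were measured, so they had no set test. Of 4 mesenchymal and fibroblast markers ACTA2, smooth muscle actin, fell 1.83-fold, over all genes and over the list alone, and the median was 0.29; on the authors' values ACTA2 differed by −0.22 and did not pass (adjusted p = 0.0619). The 3 basal markers included ITGA6 at −0.47 and CAV1 at 0.11, with a median of 0.05 and a mean of −0.10. CAV1 was detected on 1 of 2 water and 1 of 3 dilazep arrays. The CAV1 log2 fold change was −0.11 without water replicate 1 and −0.10 without dilazep replicate 1. The 4 immune and endothelial markers had a median of 0.39 and 0 passed, as with the basal markers. HLA-DRA differed by 0.64 (limma adjusted p = 0.145), and PECAM1, not above background with water, was at least 1.28-fold higher in the main fit (limma adjusted p = 0.120). The lowest log2 difference of PECAM1 over the other settings was 0.17, smaller than that bound.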

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

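The test in this part was not among those planned, and was chosen before its own result was seen. Probes without a single gene name take no part in the gene counts, and 124 of these 5636 kept probes passed the threshold when adjusted over all 20200 kept probes (limma). With dilazep 55 of them were higher and 69 lower, and over all kept probes 735 passed. This signal lies outside the comparisons by gene, and which transcripts these probes read was not analysed here.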

How the results depend on the processing

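Every alternative here was planned before the data were examined. The number of genes changed (546, with 243 higher and 303 lower) rose to 1650 (820 and 830) without background correction, 1280 (618 and 662) with an offset of 50, 1649 (797 and 852) on the authors' values and 1630 (824 and 806) with a trended robust prior. They rose to 1121 (503 and 618) without the detection filter and 1082 (524 and 558) with detection on all 5 arrays, and the cause was not tested. Without the filter too, only probes of the authors' table could have a gene symbol. Stricter thresholds left 210 (75 and 135) with a log2 difference of at least 1 and 6 (2 and 4) at an adjusted p under 0.01. Median scaling (288 higher, 242 lower), 75th percentile scaling (234 and 309), the mean of probes and array weights stayed within 1.5 times of the main count.

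Leaving out 1 array gave 0 to 107 genes changed (0 to 27 higher, 0 to 80 lower), with fewer arrays in each fit. The count was 0 without water replicate 1 (smallest adjusted p 0.125) or water replicate 2 (0.131), and 90, 91 and 107 without dilazep replicate 1, 2 and 3. All 546 calls kept their sign in each of these refits. This gives no support, because their groups did not overlap, so leaving out 1 array cannot turn the sign of the same probe. GATA2 differed by 0.79 to 0.90 in these refits without passing, and passed under each of the other settings except the block. With the replicate number as a block, 0 genes were called (0 higher, 0 lower; 2346 at an unadjusted limma p under 0.05, smallest adjusted p 0.0996) and GATA2 differed by 0.86 (adjusted p = 0.119, range over its alternatives 0.000437 to 0.201). Replicate 3 had no water array, so the block took up dilazep replicate 3 and left fewer residual degrees of freedom. Its estimates were those without that array (ALDH1A3 1.58 in both). Whether the numbers pair the arrays stayed open, and no label calls them shared. Deviations from the group means correlated at 0.0126 and 0.0167 for the numbers shared, so no strong shared effect was seen. These are not separate checks, because the deviations of 2 water arrays mirror each other. A chip as a block was not run, because the files name no chip.

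The 7 lists called with the preset correlation were called under each other refit too. Median scaling, 75th percentile scaling and the mean of probes called 8, the authors' values 9: the cytoplasmic ribosomal proteins list was added under all of these and the fatty acid list on the authors' values. With an estimated correlation 0 lists passed (smallest adjusted p 0.0580), and fry, which tests another hypothesis, called 11. The estimated correlation was 0.088 for mitosis and G2/M, 0.042 for ATF4 and 0.072 for the chaperones. It was 0.0013 for DNA replication and 0.0070 for lysosome and autophagy, under the preset of 0.01. For androgen-repressed and ribosome biogenesis genes it was −0.0026 and −0.042. In the lists under the preset, the lost calls thus did not come from a correlation above it. Called lists and named genes did not reverse under any setting. Of 607 values of called named genes under settings other than the block and the left-out arrays, 589 stayed past the threshold and 18 did not; under the block and the left-out arrays 79 of 372 did. Of the values of uncalled named genes, 24 passed under another setting. Among uncalled results, 2 gene values and 7 list medians changed sign. The number of arrays limits all of these calls, and values of probes near background rest on little signal.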

Other observations

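Of the tests in this part, those on further lists were written after the results by gene were seen and before the values of most of their own members. The exceptions were ODC1 and SRM of polyamine metabolism and CD68 of the macrophage markers, which already stood in the first lists. The test of fewer dividing cells was chosen after its value was seen. Subunits of the lysosomal proton pump (V-ATPase) were higher as a list. Of 11 measured, ATP6V1D rose 1.72-fold (limma adjusted p = 0.0314), 4 rose when adjusted over the list alone, and the median was 0.37 (camera adjusted p = 0.000431 over these later lists; with an estimated correlation adjusted p = 0.216). Beside SAT1, the 9 other measured genes of polyamine metabolism went both ways, with a median of −0.02 and a mean of 0.05, and 0 passed (camera adjusted p = 0.923). SLC7A5 fell while the 12 further amino acid transporters had a median of −0.25, with 0 called over all genes and 3 lower when adjusted over the list alone (camera adjusted p = 0.106). Of 11 nuclear lamina and envelope genes TMPO, a lamina-associated protein, fell 2.51-fold, with 1 higher and 1 lower when adjusted over the list alone (median −0.03, camera adjusted p = 0.923). Of the macrophage markers, a list written because GPNMB is also a macrophage gene, 2 were measured, AIF1 at 0.48 and CD68 at 0.12, and neither passed.

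The fall of mitosis and G2/M genes is a pattern to follow up. The normalization between arrays does not account for it, since the median nearest to 0 over 5 other ways of processing was −0.93. Brightness of the list's genes does not either, because 0% of 10000 random lists matched on level had a median as low, and the lowest of them was −0.24. As a hypothesis, fewer dividing cells may lie behind it. The DNA replication and G1/S list was also lower, with a median of −0.51. That value was seen before the test was chosen, so it is not separate support. The median of that list lay closer to 0, so a hold at one stage of the cycle stays open. The share of cells in each stage was not analysed here.

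The rise of lysosome and autophagy genes is another. The normalization between arrays is argued against by a median of 0.42 at the setting nearest to 0, and brightness of the list's genes by 0% of 10000 level-matched random lists with a median as high (the highest was 0.29). A change across lysosomal genes at large was put to 23 further lysosomal proteins that share no gene with the list. Their median was 0.26 with 0 called over all genes and, over the list alone, 5 higher and 2 lower, and the list missed the threshold set beforehand (camera adjusted p = 0.0738; with an estimated correlation adjusted p = 0.239). A missed threshold was a poor bound against this explanation, since the median lay above 0 like that of the first list. The 11 V-ATPase subunits, which also share no gene with the list, had a median of 0.37 (camera adjusted p = 0.000431, with an estimated correlation 0.216). They were not part of the test set beforehand for this explanation. Whether the lists differ was not tested, so how far the rise extends over lysosomal genes stays open.

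The level of GATA2 itself rose in cells given a compound studied for targeting it. The normalization between arrays does not explain this, since the lowest difference over 5 other ways of processing was 0.70. That the probe reads another transcript cannot be told apart from a change of GATA2, because only 1 GATA2 probe was kept. GATA2 protein and its binding to DNA were not analysed here, and a biological explanation stays untested.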
